A study of Mus musculus with 2 samples.

How the data were processed

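The series holds 2 RNA immunoprecipitation sequencing (RIP-seq) libraries from C2C12 cells, a mouse myoblast line, with 1 library per group. In one library the cells carried an adenovirus expressing Flag-tagged Zc3h10, a CCCH zinc finger protein, and RNA was recovered on anti-Flag beads. In the other the adenovirus expressed GFP. Cells were exposed to virus for 48 h at a multiplicity of infection of 5, and 10 ng of RNA was reverse transcribed from oligo(dT) primers and tagmented, per the labels' protocols. The antibody label of the GFP library reads none, while the protocol text describes Flag beads for each RIP sample, so whether the GFP library passed over the beads is not settled by the labels. No library labelled as input was used here, and whether the GFP library stands for a mock precipitation or for unselected RNA is left open.

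The authors aligned reads with TopHat2 2.0.6 to mm9 and called peaks with MACS2 2.0.9, per the submitters' processing notes. The GFP alignment was the control and the Flag-Zc3h10 alignment the treatment, per the file headers. Peaks were called on this single pair of libraries at a q-value cutoff of 0.01, with broad calling off. Tags were 51 bases long. At most 2 tags per position were kept, tags were extended to 500 bases, and the larger library was scaled to the smaller, per the file headers. The effective genome size was set to 1870000000 bases, and local control levels were taken over 1000 and 10000 bases. The Flag-Zc3h10 library had 32072310 tags, of which 10439835 (32.6%) remained after the duplicate limit, and the GFP library had 35838104, of which 10849213 (30.3%) remained. Tags are alignments in the caller's input. How reads that align to several places were treated is not given in the sources used here.

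The deposited signal is the pileup, the number of extended fragments over a peak's summit in the Flag-Zc3h10 library. The deposited fold enrichment is the ratio of that pileup to the local level expected from the GFP library. The authors' deposited −log10 p-values and −log10 q-values are the caller's own, per the file headers. Start, end, summit and width are deposited in bases of mm9 and are treated here as 1-based, since each width equals end minus start plus 1. Each of these values belongs to a peak and carries no replicate error. They are used only to describe, rank and filter peaks within the list. Because 1 library stands for each condition, no test of the conditions across replicates was possible. The caller's p-values compare these 2 libraries, and duplicated molecules without molecular identifiers are not independent.

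From the deposited values, the control level at each summit was computed as pileup divided by fold enrichment. A Poisson upper-tail probability of the pileup at this level differed from the deposited −log10 p by a median of 0.024 over the 946 peaks for which it could be computed. The genome-wide background pileup, 10439835 tags times 500 bases over the genome size, was 2.79. Peaks whose control level lay within 0.02 of it were counted as having a control at background. For these peaks the fold enrichment is bounded from below only, since the caller does not let the control fall further. Shares of peaks have 95% exact (Clopper-Pearson) binomial intervals, and these intervals and the limit of 3 counts used for a share of 0 cover counting error only. Peaks within 10000 bases of each other were joined into loci to group peaks of the same region, and within 1000 bases to measure the width of continuous regions. Peaks per placed chromosome were compared with the share of annotated genes by a two-sided exact binomial test, with Benjamini-Hochberg adjustment over 21 chromosomes. The gene shares came from a RefSeq gene table of GRCm38.p6 (49943 genes on these chromosomes), of which only the chromosome assignment was used. Correlations across peaks used 100000 permutations, two-sided. Peaks are not independent replicates. The chromosome test recovered 94.3% of planted changes (0.4-fold on X, 2-fold on 19) in 200 simulated sets of 938 peaks, and called any chromosome in 3.50% of 200 unchanged sets. The binomial test treats peaks as independent, while 397 of the 947 peaks lay in 10000-base loci of 2 or more. False calls may therefore be more frequent in these data. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

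No gene is named for any peak. The deposited list has no gene column, its positions are on mm9, and the only gene table used here is of another build. For that reason the planned assignment of peaks to genes, exons and untranslated regions was not made. The 30 gene lists fixed before the data were examined, among them iron handling, iron-sulfur cluster assembly, cardiolipin metabolism and oxidative phosphorylation, were likewise not tested. For the transcripts of the mitochondrial genome only the count of peaks is given. The rule fixed for that case names the 10 peaks with the highest fold enrichment by position. Other regions named below were chosen after their values were seen.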

Results

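RNA recovered on anti-Flag beads from C2C12 myoblasts with Flag-tagged Zc3h10 was compared with RNA from GFP-expressing myoblasts. The aim was to find the transcripts recovered with Zc3h10. The measurement was 1 peak list over 1 library per group, with 10439835 and 10849213 tags used after the duplicate limit. The list therefore has no replicate check, and the values below are those of single peaks as the authors' caller gave them. No library labelled as input was used, and whether the GFP library passed over the beads is not settled. A peak therefore does not separate recovery with Zc3h10 from a higher RNA level in cells with Flag-Zc3h10.

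The Flag-Zc3h10 library exceeded the GFP library at 947 regions of the mouse genome. Most of the excess was moderate. The median fold enrichment was 2.80, with quartiles of 1.91 and 4.12 and a range of 1.22 to 16.84. At least 4-fold enrichment was found at 246 peaks (26.0%, interval 23.2% to 28.9%) and at least 10-fold at 27 peaks (2.85%, interval 1.89% to 4.12%). At 257 peaks (27.1%, interval 24.3% to 30.1%) the excess was under 2-fold. Peaks were 500 to 32832 bases wide, with a median of 870 bases, and together covered 1181546 bases. The lowest −log10 q was 2.02, and 604 peaks (63.8%) reached a −log10 q of 10.

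The GFP library carried signal at most of these regions. The control level at the summit had a median of 50.9 fragments, against a median pileup of 122 in the Flag-Zc3h10 library. It was 100 or more at 323 peaks (34.1%, interval 31.1% to 37.2%) and under 10 at 191 peaks (20.2%, interval 17.7% to 22.9%). At 41 peaks (4.33%, interval 3.13% to 5.83%) it was at the genome-wide background of 2.79. The fold enrichment of those 41 peaks, 5.73 to 16.84 with a median of 8.96, is a lower bound. Their pileups were also low, 16 to 47 fragments.

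**Figure D1:**
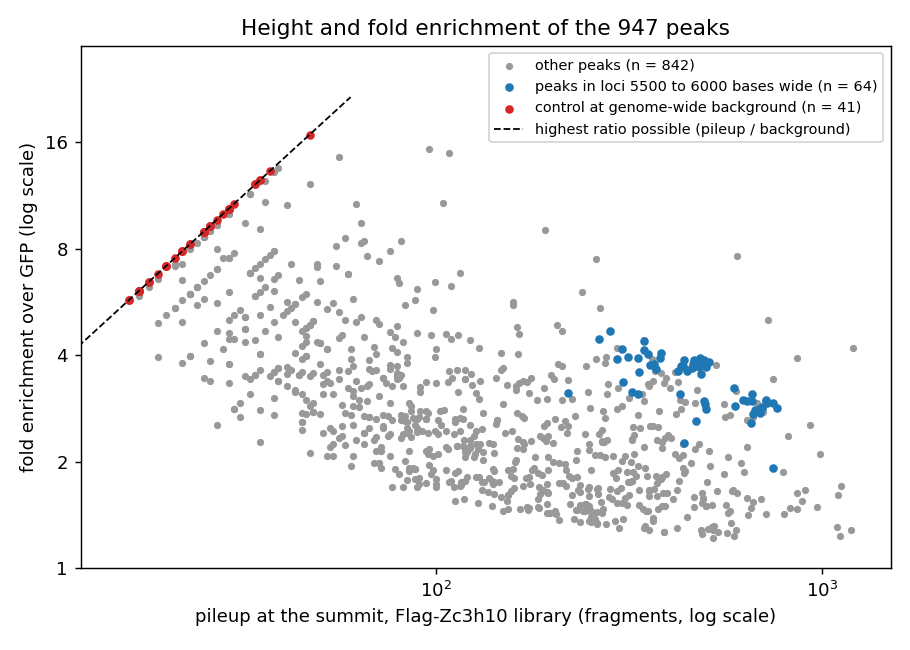
Pileup at the summit in the Flag-Zc3h10 library (x, fragments, log scale) against fold enrichment over GFP (y, log scale), 1 point per peak; red points have a control at the genome-wide background, blue points lie in loci 5500 to 6000 bases wide, and the dashed line is the highest ratio that the background of 2.79 allows. The red points lie on the dashed line, and no peak with a pileup of 500 or more exceeded a fold enrichment of 7.62.

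The 10 peaks with the highest fold enrichment lay on 8 placed chromosomes and on 1 sequence without a fixed place, and had pileups of 35 to 108 fragments. The highest ratio, at least 16.84-fold, was at chr17:34854387-34856735 (mm9), with a pileup of 47 and a control at background. The region at chr12:110781848-110784761 followed with 15.35-fold enrichment and a pileup of 96. Another peak of the 10 lay on the same chromosome at chr12:110809319-110810217, at least 12.54-fold enriched. The peak at chr14:69866115-69867887 was enriched 14.96-fold at a pileup of 108 and had a −log10 q of 81.2, the highest of these 10. The peak at chr13:56396793-56398027 was enriched 14.55-fold. The peak at chr11:49640213-49640848 was enriched 13.51-fold, at a control level of 2.89, just above background. The peak at chr8:19925705-19927180 was enriched at least 13.25-fold and that at chr1:122084199-122085152 13.16-fold. On that sequence, chr8_random, the peak at 679704 to 683677 was enriched at least 12.54-fold. The peak at chr2:130218791-130220188 was enriched 12.47-fold, and the neighbouring peak at chr2:130216520-130217258 at least 12.18-fold.

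Ranking by the caller's p-value gave other regions. The strongest was chr2:98506031-98507906, where 1202 fragments stood over a control level of 285.5 (4.21-fold, −log10 p of 355.08). The next was chr10:127980931-127982740, with a pileup of 601, a control level of 78.9 and 7.62-fold enrichment (−log10 p of 305.81). It was the only peak among the 10 strongest by p with more than 5.04-fold enrichment. After these came adjoining peaks at the proximal end of chromosome 9. The region chr9:3005807-3038638, at 32832 bases the widest of the list, was enriched 5.04-fold, and chr9:2999877-3005238 was enriched 3.94-fold. No repeat annotation was used here, so whether these chromosome 2 and chromosome 9 regions are satellite repeats, which collect reads from many places, or single transcripts was not determined. Next, chr15:36537679-36539108 was enriched 3.44-fold over a control level of 216.3. Among the 50 peaks with the highest −log10 p, 35 (70.0%, interval 55.4% to 82.1%) lay in loci 5500 to 6000 bases wide, described below. None of the 50 with the highest fold enrichment lay in such loci, where no peak exceeded 4.69-fold.

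Many peaks lay close together. Joined over gaps of up to 10000 bases, the 947 peaks formed 713 loci. Of these, 550 held a single peak and 163 held 2 or more, with 397 peaks between them. The locus chr13:93521685-93547504 held 11 peaks over 25820 bases. These 11 peaks covered 10992 of those bases and were enriched 2.94-fold to 6.43-fold with a median of 4.22, at pileups of 43 to 164 fragments. The locus chr12:81268196-81285933 held 7 peaks with a median of 2.59-fold, of which the one at chr12:81268196-81270045 reached 928 fragments. The locus chr15:36525092-36539108 held 6 peaks, enriched 1.63-fold to 3.44-fold, all at pileups of 472 or more. Loci with 5 peaks lay at chr2:51893625-51912438, chr3:80647553-80666432, chr5:130704966-130719621, chr9:65114924-65128471 and chr9:78179155-78189773, with median enrichments of 3.76, 5.89, 3.62, 4.42 and 4.75.

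**Figure D2:**
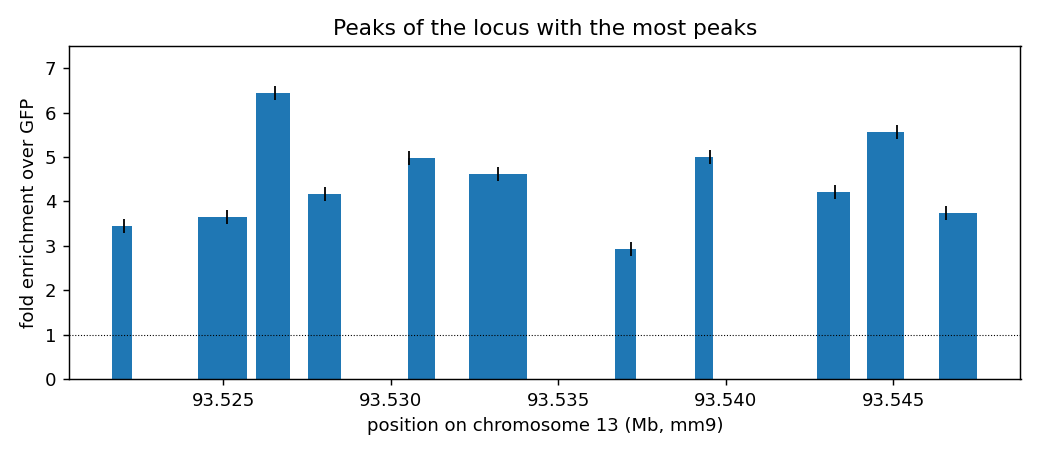
Fold enrichment over GFP (y) of the 11 peaks of the locus with the most peaks, drawn to scale along chromosome 13 (x, Mb, mm9); bars span each peak, black ticks mark summits, and the dotted line marks a ratio of 1. All 11 peaks lie between 2.94-fold and 6.43-fold.

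The X chromosome carried fewer peaks than its share of genes. It held 17 peaks where 47.2 would follow from its 2512 annotated genes, a ratio of 0.36 (interval 0.21 to 0.57; two-sided exact binomial test, adjusted p = 9.32e-06). Its peaks included 2 at chrX:50945547-50947084 and chrX:50972233-50973714, enriched 2.63-fold and 2.68-fold, and 1 at chrX:139917128-139918082, enriched 8.31-fold. The ratio stayed past the threshold in each of the 6 ways of counting genes and peaks that were run, from 0.36 to 0.49, with a highest adjusted p of 0.0406. By the same exact test, peaks were also fewer on chromosome 6 (ratio 0.56, adjusted p = 0.00296), on chromosome 14 (ratio 0.50, adjusted p = 0.00296) and on chromosome Y, which held no peak where 7.31 would follow (adjusted p = 0.00634). The expectation for Y rests on genes placed in another build, and 1 peak lay on chrY_random at 39646832 to 39647715 (5.02-fold), which was not counted there. In the exact test they were more frequent on chromosomes 8 (ratio 1.45, adjusted p = 0.0145), 19 (ratio 1.51, adjusted p = 0.0427) and 17 (ratio 1.39, adjusted p = 0.0492). Apart from X, each of these calls was lost in some way of counting. With protein-coding genes as the reference, the exact test no longer called chromosomes 17 and 19 (adjusted p = 0.223 and 0.241) and called chromosome 12 as carrying more peaks (ratio 1.72, adjusted p = 0.00213). With only protein-coding genes of established names, chromosome 8 was lost in the exact test, at a ratio of 1.32 (adjusted p = 0.102). With these genes and loci in place of peaks, the exact test no longer called chromosomes 6, 14, 17, 19 and Y, with adjusted p of 0.265, 0.292, 0.455, 0.624 and 1.0, and called chromosome 3 as carrying fewer (ratio 0.57, adjusted p = 0.0492). In that last setting Y had 17 genes and an expectation of 0.65 loci, so its count of 0 could not have been called. Which genes are expressed in these cells is not known from a peak list, so a ratio does not separate recovery with Zc3h10 from expression.

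**Figure D3:**
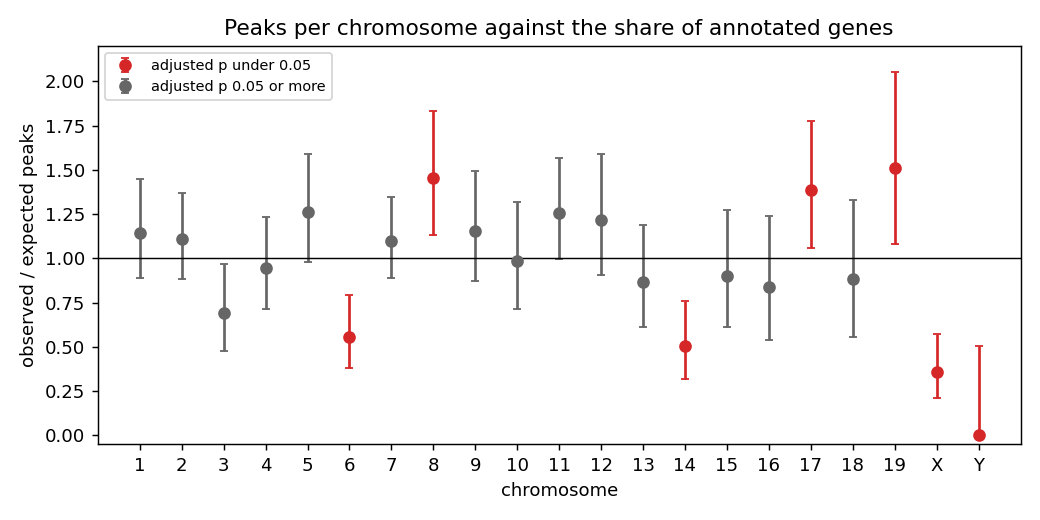
Observed over expected number of peaks (y) on each placed chromosome (x), where the expectation is the chromosome's share of 49943 annotated genes; bars are 95% exact binomial intervals and red marks an adjusted p under 0.05. The X chromosome stands at 0.36, and it was the only chromosome called in all 6 ways of counting.

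No peak was listed on the mitochondrial genome. Its 37 annotated genes, 13 of them protein-coding, therefore carried 0 of the 947 peaks, which allows a share of up to 0.317% of the list. By number of genes alone few peaks would follow, since the 389 genes of chromosome Y gave an expectation of 7.31. Gene number takes no account of transcript level, and the limit of 2 tags per position bounds the pileup in both libraries. The absence is therefore no sign of depletion, nor of a lack of recovery with Zc3h10. The list gives only regions past the caller's threshold, so it does not give the level of mitochondrial transcripts in either library, nor whether the mitochondrial sequence was part of the alignment. Zc3h10 itself lies on chromosome 10, which held 42 peaks, a ratio of 0.98 to its share of genes (adjusted p = 1.0, exact binomial test). None of them was assigned to Zc3h10 here. Peaks on unplaced or random sequences numbered 9 (0.95%, interval 0.44% to 1.80%). They included chrUn_random 5473979 to 5474921, enriched at least 12.18-fold, and chrUn_random 5495323 to 5497651, enriched 4.69-fold.

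Loci of nearly 1 width recurred over the genome. Joined over gaps of up to 1000 bases, the peaks formed 850 loci, of which 41 were between 5500 and 6000 bases wide, 2 between 5000 and 5500, and none between 6000 and 8000. The number depends on the joining: it was 18 without joining, 29 with gaps of up to 500 bases and 47 with gaps of up to 2000 bases. The 41 loci lay on 16 chromosomes and had a width of 5823 bases (median, with an SD of 110 across the 41, which the window of 5500 to 6000 bases limits). They held 64 peaks and 19.3% of all bases covered. Examples are chr11:60393218-60398997 with 713 fragments and 3.0-fold enrichment, chr5:44525986-44531890 with 493 fragments and 3.88-fold, and chrX:15051558-15057456 with 485 fragments and 3.55-fold. The loci were divided here into 2 classes at a control level of 150, after the values had been seen. In 22 loci the highest pileup was 334 to 507 fragments over a control level of 93.3 to 136.9, and enrichment at the summit was 3.12-fold to 3.92-fold with a median of 3.75. In the other 19 the highest pileup was 590 to 761 fragments over a control level of 182.1 to 387.5, and enrichment was 1.92-fold to 3.24-fold with a median of 2.87. The 387.5 and the 1.92-fold both belong to chr2:72240201-72245769, whose summit lay 720 bases from the nearer end. Without this locus the highest control level was 268.0 and the lowest enrichment 2.57-fold. The median at all loci outside the 41 was 2.68.

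**Figure D4:**
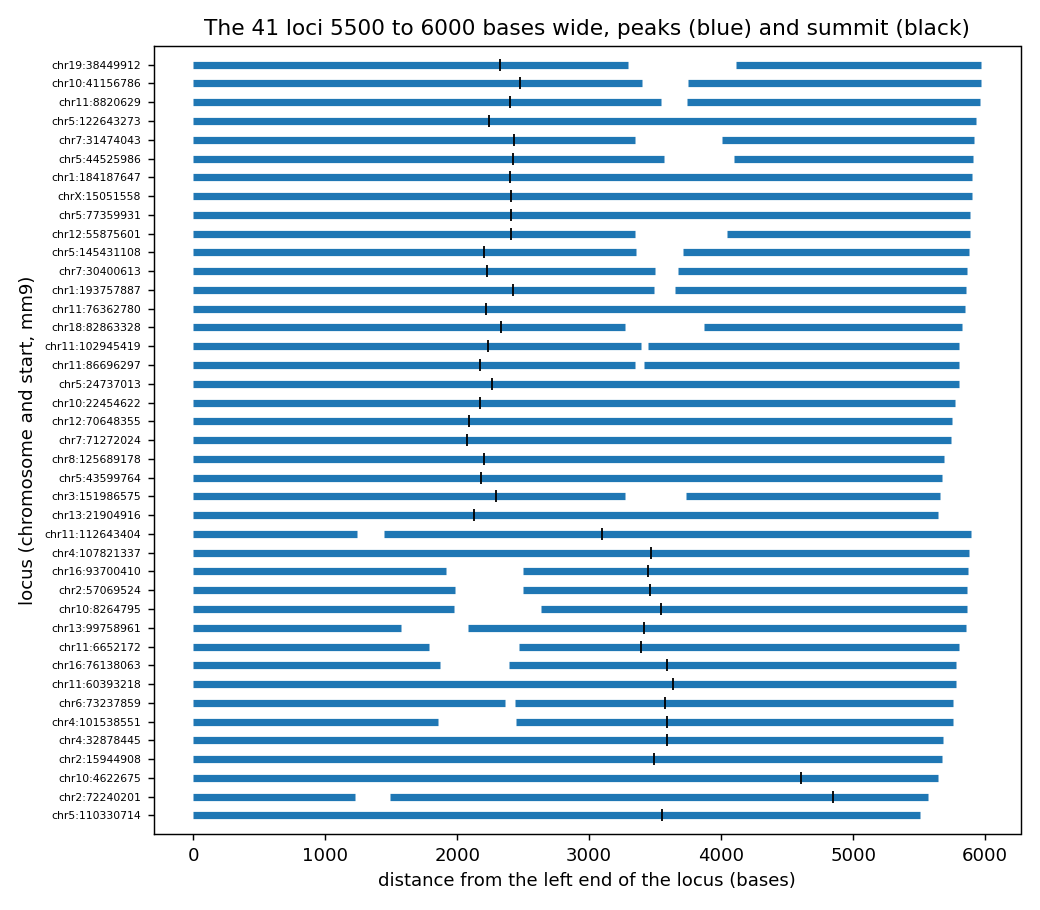
The 41 loci 5500 to 6000 bases wide, drawn from their left ends (x, bases), each row named by chromosome and start (mm9); blue bars are peaks and black ticks the summit of the highest peak. In 25 loci the summit is nearer the left end and in 16 nearer the right end, at a median of 2242 bases from the nearer end.

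Wider peaks had lower p-values and higher pileups, while fold enrichment hardly varied with width. Across peaks, Spearman's rho between −log10 p and width was 0.69 (Pearson's r 0.76 on log2 values) and between pileup and width 0.52 (r 0.54). Fold enrichment was lower at higher pileup, with a rho of -0.61 (r -0.62). Each of these 3 had a permutation p of 1e-05, the smallest that 100000 permutations can give, and an adjusted p of 1.3e-05 over the 4 relations computed. Fold enrichment and width were nearly unrelated, with a rho of 0.08 (adjusted permutation p = 0.018) and an r of 0.06 (adjusted permutation p = 0.058). Median fold enrichment was 5.73 at the 219 peaks with a pileup under 50 and 1.94 at the 86 peaks with a pileup of 500 or more. Among the 425 peaks with a pileup of at least 100 and a fold enrichment of at least 1.58, which can be called at any such pileup, the rho was 0.10 (permutation p = 0.0403). Its sign rested on the loci 5500 to 6000 bases wide, since the 361 peaks outside them gave -0.07 (permutation p = 0.157).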

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

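Settings in the plan but not listed below, on assignment to genes, features and gene lists, were not run because no annotation of mm9 was used here. The alternatives on named protein-coding genes, on 10000-base loci, on loci 5500 to 6000 bases wide and on the restricted range of pileup were chosen after seeing the data. The 947 peaks became 604 at a −log10 q of at least 10, 246 at a fold enrichment of at least 4, 850 when peaks within 1000 bases were merged and 883 without the loci 5500 to 6000 bases wide. The median fold enrichment of 2.80 was 3.24 at a −log10 q of at least 10, 2.79 on placed chromosomes and 2.70 without the loci 5500 to 6000 bases wide. The number of chromosomes past the threshold was 7, and 6 with protein-coding genes only, 5 with 10000-base loci and 7 without the loci of 5500 to 6000 bases. It was 3 with named protein-coding genes and 3 with these and 10000-base loci together. No chromosome called in the main test changed direction, and the X chromosome kept its call in every setting. The rho of -0.61 between fold enrichment and pileup stayed between -0.58 and -0.70 on placed chromosomes, per locus and without the loci of 5500 to 6000 bases. In the range where neither limit of the caller acts it turned to 0.0999 (permutation p = 0.0403), and to -0.0746 (permutation p = 0.157) when those loci were also left out. The loci of 5500 to 6000 bases numbered 41, and 29, 47 and 18 with gaps of 500 bases, 2000 bases and no joining. No paired analysis was possible because each group has 1 library. At the 41 peaks with a control at background, whose pileups were 16 to 47, the ratio is a lower bound.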

Other observations

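All tests in this part were chosen after the patterns they address had been seen. Some of the regions with the highest ratios came in neighbouring pairs with a control at or just above background. The peaks chr8:19924138-19925647 and chr8:19925705-19927180 adjoin each other and were enriched at least 10.39-fold and 13.25-fold, both with a control at background. The peaks chr2:130216520-130217258 and chr2:130218791-130220188 were enriched at least 12.18-fold and 12.47-fold. On unplaced sequence, the peaks chrUn_random 5473979 to 5474921 and 5889879 to 5890827, which are not neighbours, were 943 and 949 bases wide, with pileups of 34 and 33 and control levels of 2.79 and 2.89.

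The 41 loci of 5500 to 6000 bases are a first pattern in the list. Chance clustering of unrelated widths is argued against, since a smooth fall of locus number with width gave 1.45 loci where 41 were found (exact Poisson tail at the fitted expectation, p = 3e-44, in a window chosen after it was seen). Copies of 1 repeated element are a candidate explanation. The distance of the summit to the nearer end had an SD of 344 bases. As a percent of each locus's width, this distance had an SD of 5.63. That SD was 12.6 in the 102 other loci of at least 2000 bases and 12.3 in the 49 of at least 3000 bases. It was smaller in the 41 loci than in each of 10000 random sets drawn from either group. The log2 height had an SD of 0.306 (0.129 among the 22 loci with a control level under 150 and 0.104 among the 19 others). This was smaller than in each of 10000 random sets drawn from those 102 loci (median SD 1.18). Identical copies that share all their reads are argued against for the 41 loci as 1 set: the variance of the highest pileup was 24.7 times its mean (bootstrap interval 18.6 to 30.7), where random sharing of reads at 2 tags per position allows 2. Within the classes, which were divided after their values were seen, identical copies stay open, at 3.11 (interval 0.908 to 6.45) and 3.48 (interval 1.65 to 5.21) times the mean. The classes also differed in width, with a mean of 5855 bases (SD 80.3) in the 22 loci with a control level under 150. The mean was 5746 bases (SD 112) in the 19 others (permutation p = 0.00078). The median distance of the summit to the nearer end was 2402 and 2179 bases. Whether the classes are forms of 1 element or different elements stays open. An element of this kind may be an endogenous retrovirus, and reads shared between copies could give 1 RNA species many peaks, but neither the repeat annotation nor the alignments were used here. Whether such an RNA was retained on the Flag beads or was more abundant in cells with Flag-Zc3h10 cannot be told apart, because its 3.55-fold median enrichment over both classes is over the GFP library, whose passage over the beads is not settled.

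The lower fold enrichment at higher pileup is a second pattern. The calling threshold could account for part of it, since a low ratio is called only at a high pileup. The background floor works the other way, as it caps the ratio at pileup over 2.79, which rises with pileup. The highest fold enrichment was 16.84 at pileups under 50, 15.35 at 50 to 100 and 14.96 at 100 to 300. It was 4.41 at 300 to 500 and 7.62 at 500 or more, so the maxima were lower only from 300 upward. A lower limit on called ratios does not set these maxima. In the range where neither limit acts the relation was weak (rho 0.0999, and -0.0746 without the loci of 5500 to 6000 bases, on which the positive sign rests). That range of values is also narrower, which weakens any relation. The limit of 2 tags per position stays open as a further cause. The highest pileup reached 60.1% of the 2000 fragments this limit allows, and a lower local bound in short exons was not measured.

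The peak chr10:127980931-127982740 ranked 2 by −log10 p, on the chromosome that holds Zc3h10. Transgene-derived Zc3h10 RNA may be its source, as the Zc3h10 virus carries its coding sequence and the GFP virus does not. This stays open. The rank alone is weak evidence, since 1 of the 2 strongest peaks would fall on chromosome 10 by its number of peaks in 8.68% of cases, and the position was not compared with an mm9 annotation.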
